A study of Mus musculus with 12 samples.

How the data were processed

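Polyadenylated RNA from isolated mouse cardiomyocytes was sequenced in 12 libraries. The labels place them in 4 groups of 3: sham operation with saline, sham operation with JV001, a CKD model with saline and the CKD model with JV001. The CKD model combined AngII, a high salt diet and removal of 1 kidney. Per the labels' protocols, RNA was extracted with an RNeasy plus mini kit and 1.3 ug of total RNA entered a VAHTS Universal V6 library. The labels give 12 weeks for 3 of the groups and no duration for the CKD saline group. Nothing in the labels says that replicates were separate animals, so the p-values measure only the spread between these samples, which may be technical.

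The deposited counts are whole numbers of reads per gene symbol that the authors left unnormalised, with 22584 genes. Per the submitters' processing notes, fastp, HISAT2 and HTSeq and the build GRCm39 were used. Their versions, the annotation, the counting mode and the strand setting are not given in the sources used here. The deposited FPKM values were made by the authors from the same counts: in 10212 genes with at least 50 reads in each library, count per gene length and library total gave the FPKM with 1 whole-number length per gene in 100% of genes, at a tolerance of 0.01. Column names were matched to the labels by group initials and replicate number, with C read as the CKD saline group. Of the gene names, 18697 were found in the reference table of symbols, and all names were used as deposited.

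Library totals ran from 25.2 to 37.0, in units of 1e6 counts. A count of 0 in a library allows up to 3 counts, and such limits cover counting error only. Genes in near-identical copies, such as the haemoglobin genes Hbb-bs and Hbb-bt, and the genes of the mitochondrial genome, which have nuclear copies, are uncertain where the counting could split their reads. The strand setting was not stated, so reads of overlapping and antisense genes cannot be separated.

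The test was edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr by group (minimum count 10) and the quasi-likelihood F test. All 12 libraries entered 1 fit of 4 group means, and p-values were adjusted by Benjamini-Hochberg over 15004 genes, with a threshold of 0.05. The contrasts were CKD saline against sham saline, CKD JV001 against CKD saline, sham JV001 against sham saline, CKD JV001 against sham JV001, and the interaction of CKD and JV001. Normalised expression is in CPM (counts per 1e6 counts) with TMM factors, as mean ± SD. Log2 CPM used a prior count of 2. Standard errors (SE) are of log2 fold changes.

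There were 23 pathway lists and 14 lists of cell type markers, with 629 different symbols written and 622 found, of which the table's older or mitochondrial names were matched by a hand-written alias table. The 35 lists with 5 or more tested members were tested with camera (limma 3.58.1) at the preset correlation of 0.01, adjusted over lists within a contrast. Camera compares a list with all other genes. Adipocyte and sex-linked markers had too few tested members. Some lists share genes, so they do not give separate results. Every ventricular marker is also in the contractile and calcium handling list. Several fibroblast markers, such as Dcn, Col1a1 and Postn, are also in the extracellular matrix list. Nppa, Myl4 and Myl7 are in both the atrial marker list and the hypertrophy and fetal programme list. Members were counted after adjustment over all genes and adjusted over the list alone. Camera with an estimated correlation and fry were the alternatives. Fry asks whether a list's genes move on balance 1 way, or in either direction, and compares them with no other genes.

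Named genes followed a rule: up to 10 higher and 10 lower genes by fold change that passed, did not overlap between groups and reached 1 CPM; up to 4 members per list by adjusted p; all shelterin members, with Terf1, Terf2 and Tert per library; and, where fewer than 5 genes passed, the 5 with the smallest p. Names of the form Gm plus a number and names ending in Rik or -ps were left out, while names starting with LOC were kept. Genes called in both contrasts in opposite directions were to be named as reversed; edgeR called 0 genes in either, so this could not apply.

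The design, the lists, the rule and a set of other settings were fixed before the data were examined. These settings were RLE factors, no filter, a stricter filter (1 CPM in 3 libraries and a mean of 10 reads), the DESeq2 1.42.0 Wald test, only the groups compared, a replicate block, each library left out, mitochondrial and haemoglobin genes left out, limma on log2(FPKM + 1) or log2(FPKM + 0.1) for genes with a mean FPKM of at least 0.5, and, for the fold change correlations, genes of at least 10 CPM. Further alternatives were chosen after seeing the data: leaving out library 3 of both CKD groups, a robust spread, limma voom with quality weights per library, summing libraries 1 and 2 within each CKD group, and a covariate of fibroblast, endothelial, smooth muscle and macrophage marker levels.

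Replicates were compared before averaging. Every pair of libraries differed by more than counting noise. CKD saline libraries 1 and 2 had a chi-square per degree of freedom of 8.02 and a Spearman correlation of 0.990, against 182 and 0.944 for libraries 1 and 3. They were kept as separate replicates, and the sum is among the alternatives.

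The labels number the replicates 1 to 3 in every group. Same-numbered libraries of the CKD saline and CKD JV001 groups deviated together from their group means, with correlations of 0.296, 0.289 and 0.492, all above the limit of 0.1. By that rule the numbers would pair these groups, from the values and not from the labels. Libraries 1 and 2 lay close together within both groups, with Spearman correlations of 0.990 and 0.993. The correlations of deviations may therefore reflect library 3 alone. They cannot show that the libraries 1, or the libraries 2, belong together. No other pair of groups met it.

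The scripts were tested on simulated counts with the real spread, with 100 genes changed 2-fold and 100 changed 4-fold among 15004. In CKD saline against sham saline, 17% and 75% were recovered. In CKD JV001 against CKD saline the shares were 18% and 68%. In sham JV001 against sham saline they were 9% and 72%, and in CKD JV001 against sham JV001 18% and 78%. In the interaction they were 0% and 34%. A changed list passed camera in each of the 5 contrasts, and 0 of 22 to 25 untouched lists did. The simulated genes were drawn independently of each other. This therefore gives no rate of false calls for lists whose genes are correlated.

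Fold changes of contrasts with shared libraries were correlated across genes and set beside 50 simulations of unchanged groups and 100 random assignments of the libraries, which ignored the pairs. The simulations drew genes independently of each other. The expected covariance with the pairs, from the deviations of log2 CPM from group means, and the 8 swaps within pairs were added after seeing the data.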

Results

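RNA was measured in cardiomyocytes isolated from hearts of C57BL6 mice. The 12 libraries formed 4 groups of 3: sham operation with saline or with JV001, and a model called CKD in the labels (AngII, high salt diet and removal of 1 kidney) with saline or with JV001. JV001 is known here only by its code name, and the series title speaks of gene therapy that recaps telomeres in a cardiorenal syndrome. Total counts per library, in units of 1e6 counts, averaged 35.7 ± 2.23 in sham saline, 33.8 ± 0.946 in sham JV001, 29.3 ± 4.17 in CKD saline and 32.3 ± 1.80 in CKD JV001 (SD, n = 3).

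Markers of ventricular cardiomyocytes were abundant in each library, and markers of fibroblasts, endothelial cells and macrophages were also present at levels that differed between libraries of 1 group. CKD saline library 3 had a mean fibroblast marker level of 6.29 log2 CPM, against 4.34 and 4.32 in CKD saline libraries 1 and 2. Its ventricular marker level was 11.79 log2 CPM, against 12.60 and 12.61. CKD JV001 library 3 had the lowest ventricular marker level of the 12 libraries, 10.71 log2 CPM, and a neutrophil marker level of 5.10 log2 CPM against 0.63 and 0.31 in the other libraries of its group. The first principal component held 52.3% of the variance. CKD JV001 library 3 lay at 138 on it and CKD saline library 3 at 62.5, whereas CKD saline libraries 1 and 2 lay at -51.5 and -50.1. By Spearman correlation, 8 of 12 libraries were nearest to a library of their own group. CKD saline library 3 was nearest to CKD JV001 library 2, at 0.986.

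**Figure D1:**
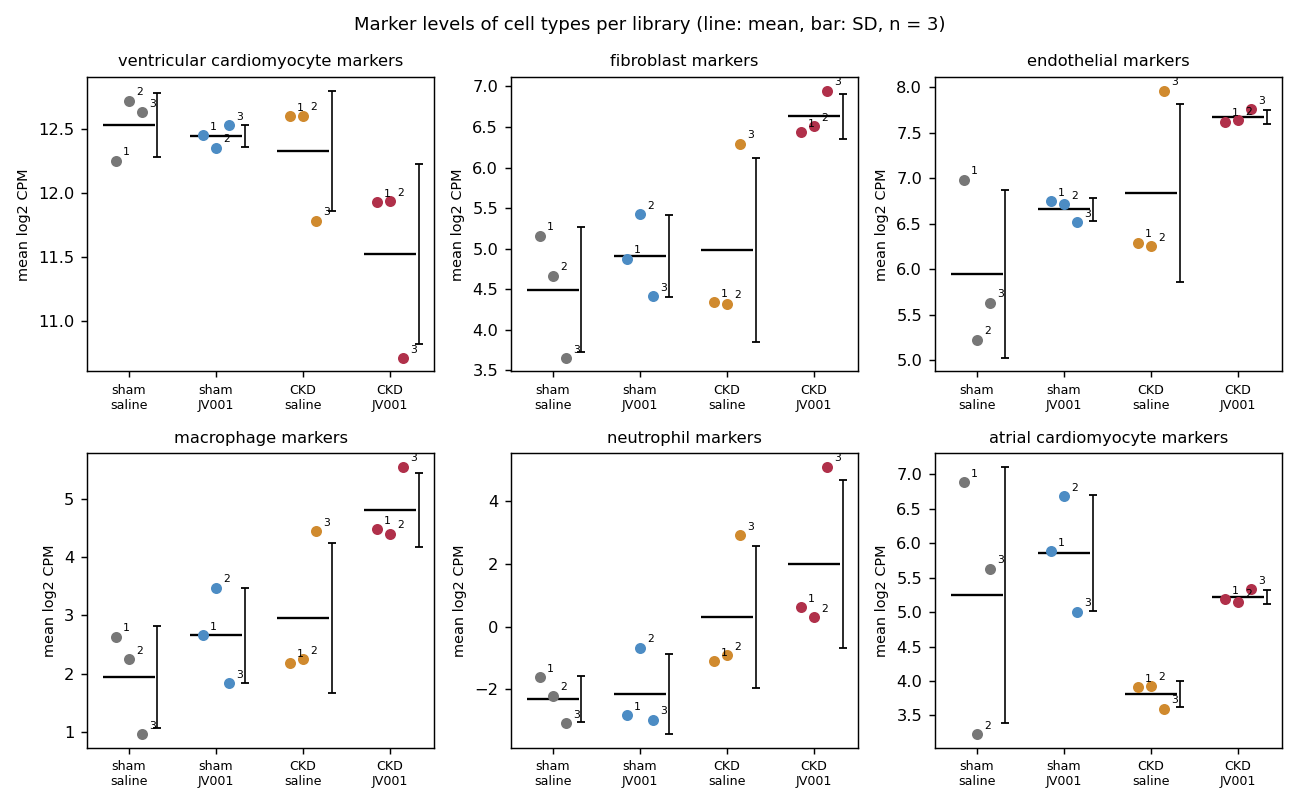
Mean log2 CPM of the markers of 6 cell types in each library, by group, with points numbered by replicate, a line at the mean and a bar of 1 SD (n = 3). Libraries 1 and 2 of the CKD saline group lie together in each panel, and its library 3 has a higher fibroblast level, 6.29 against 4.34 and 4.32.

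Because the series title speaks of telomeres, genes of the telomere cap were read first. Terf2, which binds telomeric DNA in the shelterin complex, lay between 10.9 and 14.1 CPM in the 12 libraries. Its mean was 12.4 ± 0.581 CPM in sham saline, 12.8 ± 1.67 CPM in sham JV001, 11.7 ± 0.0733 CPM in CKD saline and 12.5 ± 0.610 CPM in CKD JV001 (SD, n = 3). Terf1, another shelterin protein that binds telomeric DNA, had 2.02 to 4.51 CPM in the sham libraries. It had 3.07, 2.24 and 5.20 CPM in CKD saline libraries 1 to 3, and 3.39, 4.40 and 8.95 CPM in CKD JV001 libraries 1 to 3. Tert, the catalytic subunit of telomerase, had 3, 1 and 4 reads in sham saline, 6, 0 and 0 in sham JV001, 0, 0 and 3 in CKD saline and 0, 0 and 0 in CKD JV001, where 3 reads are the limit that a count of 0 allows. It had too few reads to be tested.

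The 7 shelterin genes (Terf1, Terf2, Terf2ip, Tinf2, Acd, Pot1a and Pot1b) passed edgeR's test in 0 of the 5 contrasts, also when adjusted over the list alone. Their log2 fold changes ran from -0.23 to 0.67 in CKD JV001 against CKD saline, where the smallest adjusted p was 0.323, and from 0.05 to 0.30 in sham JV001 against sham saline, where it was 0.9997. They ran from -0.08 to 0.46 in CKD saline against sham saline (smallest adjusted p 0.941) and from -0.21 to 0.87 in CKD JV001 against sham JV001 (smallest adjusted p 0.149). The log2 fold change of Terf2 was 0.09 (SE 0.14, adjusted p 0.684) with JV001 in CKD and 0.05 (SE 0.14, adjusted p 0.9997) with JV001 in sham. That of Terf1 was 0.67 (SE 0.43, adjusted p 0.346) and 0.30 (SE 0.43, adjusted p 0.9997). The first was 0.15 without CKD JV001 library 3, 1.07 without CKD saline library 3 and 0.45 without CKD saline library 2. The second was 0.51 without sham saline library 1, 0.12 without sham saline library 3 and 0.10 without sham JV001 library 1. In the interaction Terf1 had 0.37 (SE 0.60), or -0.15 without CKD JV001 library 3, and Terf2 0.05 (SE 0.20). Telomerase and telomere maintenance genes, 19 tested, had medians between -0.06 and 0.02 and did not pass camera in any contrast. Adjusted over the list alone, 1 of them was lower in CKD JV001 against sham JV001. Reads were counted on the mouse build GRCm39, and what JV001 carries is not known here. These counts therefore cannot show whether RNA made from JV001 was present.

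**Figure D2:**
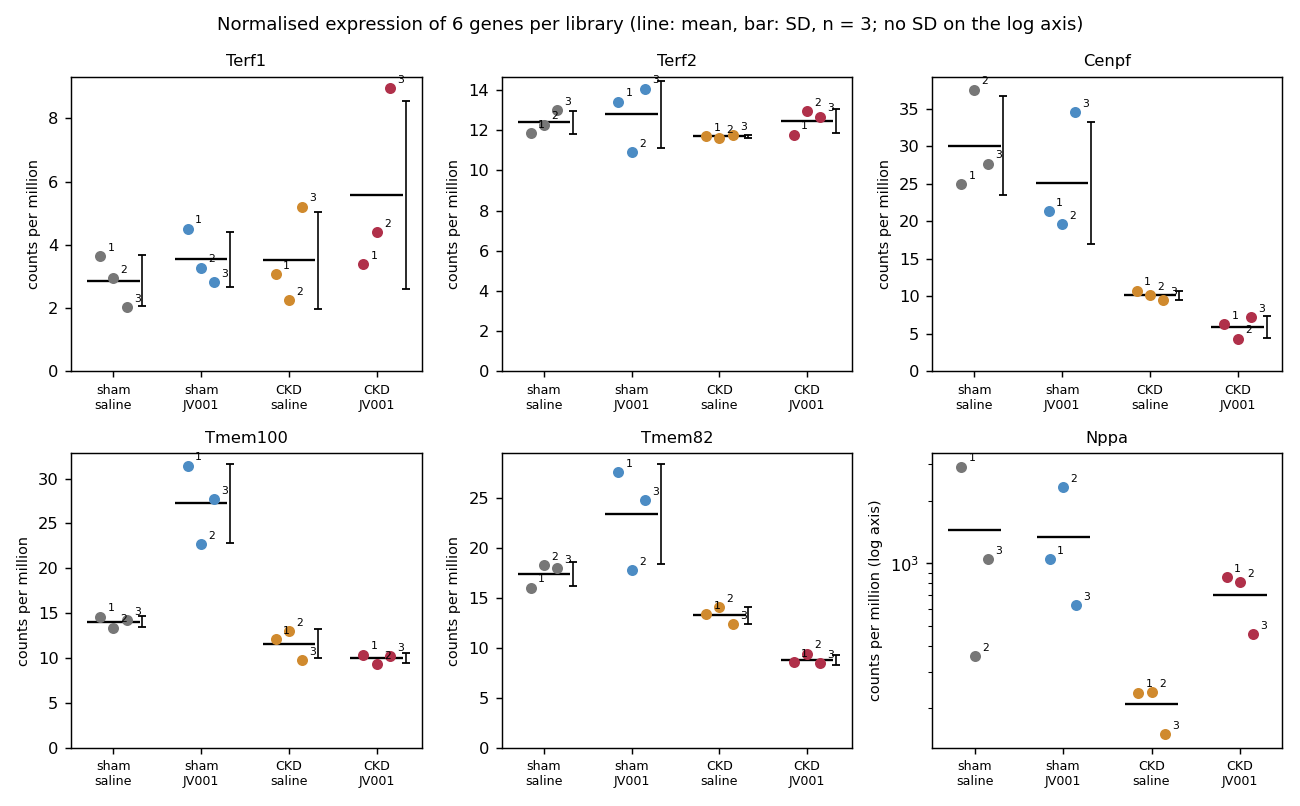
Normalised expression in CPM of 6 genes in each library, by group, with points numbered by replicate, a line at the mean and a bar of 1 SD (n = 3); Nppa is on a log axis without the bar. Terf2 lies between 10.9 and 14.1 CPM throughout, and Cenpf averages 10.1 CPM in CKD saline and 5.94 CPM in CKD JV001 against 30.04 CPM in sham saline.

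CKD saline against sham saline asked what the CKD model changed in these cells. Atrial cardiomyocyte markers fell, with a median log2 fold change of -2.79 and 7 of 9 genes negative by camera at its preset correlation. Neither this list nor any other passed in that contrast with an estimated correlation (smallest adjusted p 0.589) or fry (0.663). Nppa, the atrial natriuretic peptide, was at 208 ± 51.0 CPM against 1441 ± 1328 CPM (SD, n = 3). Myl7, the atrial light chain, was at 17.0 ± 5.47 against 216 ± 247 CPM and Sln, sarcolipin, at 5.46 ± 1.57 against 66.0 ± 77.6 CPM. These markers varied widely among the sham saline libraries, and without sham saline library 1 the log2 fold changes of Nppa, Myl7 and Sln, -2.79, -3.67 and -3.59, were -1.75, -2.21 and -2.04. Genes of the mitochondrial genome rose, with a median of 0.57 and 13 of 13 positive, including COX2 at 1.17 (SE 0.44) and ATP6 at 1.55 (SE 0.42). Cardiac ion channel and gap junction genes fell (median -0.30), with the T-type calcium channel Cacna1h at -1.77 (SE 0.41). The median of atrial markers was -1.73 and that of mitochondrial genome genes 0.98 without sham saline library 1, and that of ion channel genes was -0.18 without CKD saline library 3.

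Single genes did not pass in that contrast: edgeR called 0 of 15004 genes, 743 had an unadjusted p under 0.05 where chance gives 750.2, and the smallest adjusted p was 0.234. DESeq2 called 54 genes (14 higher, 40 lower), limma on FPKM 0 with either pseudocount, and voom with quality weights 5. Groups did not overlap in 10.6% of genes, where chance gives 10%. The genes with the smallest p were Egr3, an immediate early transcription factor (log2 fold change 2.82, SE 0.39, adjusted p 0.234), Ptger4, a prostaglandin E2 receptor (2.40, SE 0.36, adjusted p 0.236), the centromere gene Cenpf (-1.57, SE 0.26, adjusted p 0.405), the phosphodiesterase Pde3a (-0.90, SE 0.16, adjusted p 0.434) and the iron exporter Slc40a1 (-0.87, SE 0.16, adjusted p 0.610). The 743 genes became 1409 without sham saline library 1, 495 without library 2 and 494 without library 3.

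Markers of other cell types rose in the same contrast, with medians of 3.70 for neutrophils, 2.91 for erythroid cells, 1.26 for macrophages, 0.89 for endothelial cells and 0.68 for fibroblasts, though 0 lists passed with an estimated correlation (smallest adjusted p 0.589). Leaving out CKD saline library 3, these medians were 0.92, 0.56, 0.10, 0.08 and -0.23. Several neutrophil markers had few reads in sham saline libraries 1 to 3, such as Mmp8 with 0, 0 and 0 and S100a8 with 9, 1 and 7. The size of the neutrophil median is therefore uncertain. S100a9, a neutrophil protein, was at 12.0 ± 18.0 against 0.349 ± 0.423 CPM, Hbb-bt at 16.1 ± 21.4 against 2.00 ± 1.41 CPM and C1qb at 26.2 ± 25.1 against 9.97 ± 4.65 CPM (SD, n = 3); their log2 fold changes of 5.16, 3.01 and 1.40 were 2.33, 0.95 and 0.27 without CKD saline library 3. Inflammation and NF-kB (0.87), interferon response and DNA sensing (0.63), extracellular matrix and fibrosis (0.41) and cell cycle genes (0.68) also rose. Immediate early and dissociation stress genes passed camera as higher with a median of 0.06, which was -0.07 without sham saline library 3, 0.32 without sham saline library 2, 0.14 without CKD saline library 2 and 0.04 without CKD saline library 1. In the matrix list Cilp had 2.34 (SE 0.67) and Ltbp2 1.48 (SE 0.48), or 0.96 and 0.65 without CKD saline library 3. Ccl5 of the inflammation list had 3.68 (SE 0.96), at 0.403 against 0.0282 CPM. Its sham saline mean lay below the limit of 3 counts, 0.0811 to 0.0906 CPM there, so this fold change is uncertain. Hypertrophy and fetal programme (-0.23), mitochondrial biogenesis (-0.20), contractile and calcium handling (-0.17), fatty acid oxidation (-0.17) and nuclear oxidative phosphorylation genes (-0.09) fell. In the cell cycle list Cenpf was lower, as the only member that passed when adjusted over the list alone. Without CKD saline library 3 the medians were -0.38 for matrix, -0.27 for inflammation, 0.08 for interferon, -0.05 for hypertrophy, 0.00092 for mitochondrial biogenesis, 0.10 for contractile, 0.08 for fatty acid oxidation and 0.16 for oxidative phosphorylation genes. Without sham saline library 1 they were 1.00 for matrix, 1.42 for inflammation, 1.22 for interferon, 1.13 for fibroblast and 1.55 for endothelial genes, -0.32 for mitochondrial biogenesis, -0.30 for contractile, -0.27 for fatty acid oxidation and -0.20 for oxidative phosphorylation genes. For hypertrophy, contractile, fatty acid oxidation and oxidative phosphorylation genes they were -0.05, -0.10, -0.07 and -0.01 without sham saline library 2, where mitochondrial biogenesis genes had -0.13. They were -0.15, -0.07, -0.08 and -0.03 without sham saline library 3, where matrix genes had 0.17 and fibroblast markers 0.38. They were -0.36, -0.32, -0.29 and -0.21 without CKD saline library 2, with matrix genes at 0.72. Contractile genes had -0.30, fatty acid oxidation -0.26, oxidative phosphorylation -0.23, mitochondrial biogenesis -0.33 and matrix genes 0.73 without CKD saline library 1.

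In all, 18 of 35 lists passed camera in that contrast, 11 higher and 7 lower, at adjusted p between 1.98e-11 and 0.0450. With an estimated correlation none of these passed (adjusted p 0.589 to 0.767), and fry passed 0. Adjusted over the list alone, 6 atrial, 4 hypertrophy, 1 ion channel, 1 fatty acid oxidation and 1 cell cycle genes were lower, and 4 erythroid, 1 mitochondrial genome and 1 immediate early genes were higher. The hypertrophy list shares Nppa, Myl4 and Myl7 with the atrial list, so its fall is not a separate result. Without CKD saline library 3, 8 lists passed. Extracellular matrix and fibrosis then had a median of -0.38 (adjusted p 0.00803) and nuclear oxidative phosphorylation 0.16 (adjusted p 0.00916), both in the opposite direction. Fibroblast markers then had -0.23, contractile genes 0.10 and fatty acid oxidation genes 0.08, and endothelial (0.08), macrophage (0.10), interferon (0.08), inflammation (-0.27), erythroid (0.56), hypertrophy and mitochondrial biogenesis lists did not pass. Without sham saline library 3, matrix (0.17), fibroblast (0.38), inflammation, interferon, contractile, fatty acid oxidation and oxidative phosphorylation lists did not pass. Without sham saline library 2, contractile, fatty acid oxidation, oxidative phosphorylation and mitochondrial biogenesis lists did not pass, and immediate early genes did not without sham saline library 1, without sham saline library 3 or without CKD saline library 3. Atrial, mitochondrial genome, ion channel, cell cycle and neutrophil lists passed whichever library was left out.

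CKD JV001 against CKD saline asked how JV001 acted in the CKD model. Interferon response genes rose with a median log2 fold change of 2.32 (29 of 29 positive) and inflammation genes with 2.69 (22 of 22), and adjusted over the list alone 28 and 18 of them were higher. These calls were by camera at its preset correlation, and 0 lists passed with an estimated correlation (smallest adjusted p 0.437) or fry (0.167). CKD JV001 library 3 carried much of them: its mean interferon level was 6.85 log2 CPM against 4.22 and 4.17 in CKD JV001 libraries 1 and 2, and without it the medians were 0.85 and 0.55, and Cxcl10 had 1.62, Dhx58 1.46, Usp18 1.05, Il6 2.62 and Socs3 1.37 on the log2 scale. The interferon-induced chemokine Cxcl10 was at 74.4 ± 126 CPM against 0.609 ± 0.298 CPM (SD, n = 3), the RNA sensor Dhx58 had a log2 fold change of 2.60 (SE 0.62), Usp18 2.40 (SE 0.65), the cytokine Il6 5.45 (SE 1.52) and Socs3 2.08 (SE 0.56). Il6 averaged 0.117 CPM in CKD saline, within the limits of 3 counts there (0.0894 to 0.119 CPM), so its fold changes are uncertain. Extracellular matrix genes rose (median 1.20, 38 of 38 positive), and Postn, a matrix protein of activated fibroblasts, was at 65.1 ± 6.89 against 24.4 ± 22.0 CPM. Contractile and calcium handling genes fell (median -0.72, 26 of 26 negative), as did nuclear oxidative phosphorylation (-0.66, 40 of 40), fatty acid oxidation (-0.71) and glucose uptake and glycolysis genes (-0.63). Myh6, the adult heavy chain of cardiac myosin, was at 14292 ± 4628 against 25037 ± 7809 CPM. Without CKD JV001 library 3 the medians were -0.41 for contractile, -0.38 for oxidative phosphorylation, -0.43 for fatty acid oxidation and -0.35 for glycolysis genes. Without CKD saline library 3 that of matrix genes was 2.23 and Postn passed edgeR at 2.47 (adjusted p 0.0287) against 1.42, as did Myh6, Dhx58, Usp18, Il6 and Socs3. The CKD saline libraries left in that fit may come from 1 animal, so these passes may rest on technical spread.

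Among those groups, Ttn had -0.92 (SE 0.31), the calcium release channel Ryr2 -0.88 (SE 0.29), citrate synthase Cs -0.81 (SE 0.29), Sdha -0.76 (SE 0.28), the hexokinase Hk2 -0.92 (SE 0.33) and Decr1 -0.84 (SE 0.30). Ltbp2 had 1.60 (SE 0.47) and Mmp2 1.46 (SE 0.50). Mitochondrial biogenesis (-0.54), cardiac ion channel (-0.61) and autophagy genes (-0.22) also fell, with Ppara at -0.84 (SE 0.25) and Opa1 at -0.84 (SE 0.28), and senescence and secretory factors (1.24), integrated stress (0.40) and immediate early genes (0.38) rose. Ventricular cardiomyocyte markers, all of them also in the contractile list, fell (-0.74, 12 of 12 negative). Markers of fibroblasts (1.36), macrophages (1.496), smooth muscle and pericytes (1.10) and the epicardium (1.52) rose. So did those of endothelial cells (0.76), atrial cardiomyocytes (1.85), T and NK cells (1.35) and B cells (1.03). Several fibroblast markers are also in the matrix list, so the overlapping lists do not give separate results. Dcn was at 579 ± 94.9 against 226 ± 176 CPM and Nppa at 706 ± 219 against 208 ± 51.0 CPM. The log2 fold change of Pdgfra was 1.498 (SE 0.57), of Ccr2 1.84 (SE 0.73) and of Mrc1 1.77 (SE 0.79). Without CKD JV001 library 3, Ccr2 had 0.81 and Mrc1 0.90. Mrc1 (2.98, adjusted p 0.0375), Pdgfra (2.29), Dcn (2.22), Ltbp2 (2.44) and Mmp2 (2.26) passed edgeR without CKD saline library 3, as did Ttn, Ryr2, Cs, Sdha, Hk2, Decr1, Ppara and Opa1. The CKD saline libraries left in that fit may come from 1 animal. Again 0 of the lists named here passed with an estimated correlation. Without CKD JV001 library 3 the medians were -0.41 for ventricular markers, -0.33 for ion channel, -0.30 for mitochondrial biogenesis, -0.09 for autophagy, 0.66 for senescence, 0.13 for integrated stress and 0.22 for immediate early genes, and 0.56 for smooth muscle markers. Without CKD saline library 3 they were 2.30 for fibroblast, 2.76 for macrophage, 1.79 for smooth muscle, 1.56 for endothelial, 3.95 for T and NK cell and 4.23 for B cell markers, 1.99 for senescence, 0.78 for immediate early and -0.82 for mitochondrial biogenesis genes. Endothelial markers had 0.48 without CKD saline library 1 and 0.48 without library 2, where T and NK cell markers had 0.77 and 0.79 and B cell markers 0.62 and 0.68. Several T, NK and B cell markers lay near the limit of 3 counts in CKD saline libraries 1 and 2. There Cd3e had 0 and 0 reads, Cd2 0 and 1 and Cd79a 0 and 6, so the size of these medians is uncertain.

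In this contrast edgeR called 0 of 15004 genes, with 2707 at an unadjusted p under 0.05 and a smallest adjusted p of 0.276. DESeq2 called 67 genes (44 higher, 23 lower), limma on FPKM 0 with either pseudocount and voom with quality weights 6738 (3777 higher, 2961 lower). Groups did not overlap in 14.3% of genes, where chance gives 10%. Without CKD saline library 3, edgeR called 3287 genes (2039 higher, 1248 lower), with 6579 at p under 0.05. The latter number was 763 without CKD saline library 1, 769 without CKD saline library 2 and 924 without CKD JV001 library 3, with 0 genes called. The smallest p belonged to Zfp703 (0.92, SE 0.19), LOC118568062 (-1.33, SE 0.29), the secreted protein Angptl2 (0.83, SE 0.18), Camk2b (-1.40, SE 0.31) and the transcription factor Tbx18 (1.29, SE 0.29), each at an adjusted p of 0.276 in edgeR.

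Of 35 lists, 22 passed camera with JV001 in CKD, 14 higher and 8 lower, and none passed with an estimated correlation (adjusted p 0.437 to 0.679) or with fry (smallest 0.167). Adjusted over the list alone, 1 immediate early gene was higher and 1 lower, and the lists other than interferon and inflammation had 0. The calls held without each library except for integrated stress (without CKD saline library 3, adjusted p 0.242, or CKD JV001 library 3, 0.372), autophagy (CKD saline library 2, 0.0739, or CKD JV001 library 3, 0.0862), immediate early genes (each CKD saline library, 0.0529 to 0.102, or CKD JV001 library 3, 0.339), atrial markers (CKD saline library 3, 0.214), and T and NK cell and B cell markers (CKD saline library 1, 0.0975 and 0.102, or CKD JV001 library 1 or library 2). With replicate number as a block, immediate early genes had an adjusted p of 0.0520 and did not pass. With the marker levels of other cells as a covariate, 11 lists passed, 5 of them among the 22 irrespective of direction. The covariate itself holds the fibroblast, endothelial, smooth muscle and macrophage markers.

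**Figure D3:**
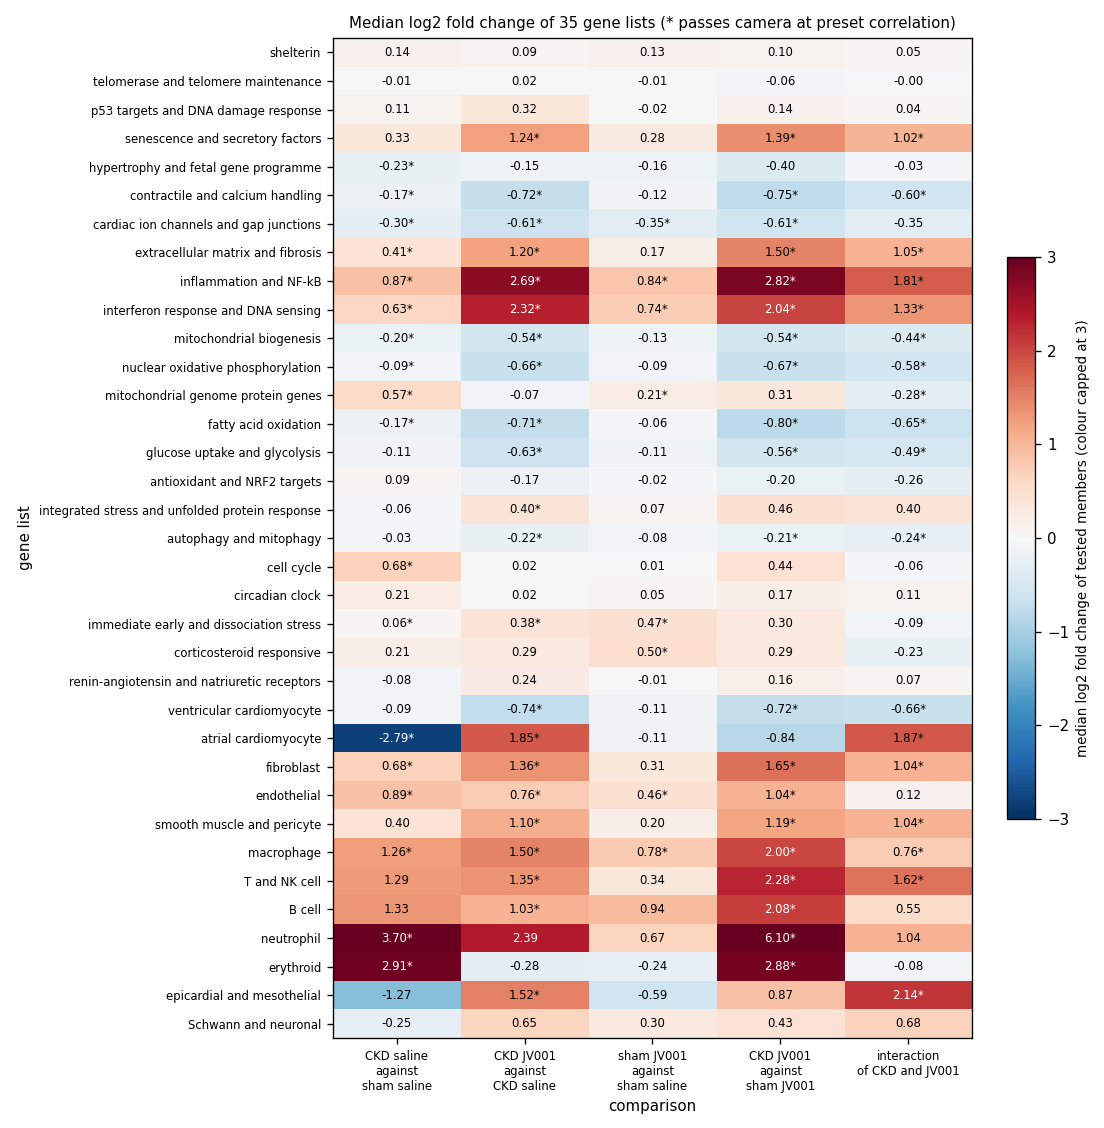
Median log2 fold change of the tested members of 35 gene lists (rows) in 5 comparisons (columns), with an asterisk where camera at the preset correlation passed an adjusted p of 0.05; 0 lists passed with an estimated correlation. Interferon response genes have 0.63 in CKD saline against sham saline and 2.32 in CKD JV001 against CKD saline; under scaling to library totals the immediate early list of the first column turns to -0.02.

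Sham JV001 against sham saline asked how JV001 acted without the CKD model. Corticosteroid responsive genes rose with a median log2 fold change of 0.50 (15 of 16 positive) by camera at its preset correlation. Neither this list nor any other passed in that contrast with an estimated correlation (smallest adjusted p 0.976) or fry (0.988). Zbtb16, a transcription factor induced by glucocorticoids, was at 214 ± 92.7 CPM against 66.4 ± 36.0 CPM (SD, n = 3), and Sgk1, a kinase induced by corticosteroids, at 142 ± 32.9 against 71.1 ± 47.0 CPM. Interferon response (0.74), inflammation (0.84), immediate early (0.47) and mitochondrial genome genes (0.21) rose as well, with Oas2 at 1.61 (SE 0.92), Ifi44 at 1.51 (SE 0.89), Egr1 at 0.65 (SE 0.29) and Klf4 at 1.01 (SE 0.47). Endothelial (0.46) and macrophage markers (0.78) rose with them, and the endothelial gene Flt1 had 1.01 (SE 0.54) and Fabp4 0.94 (SE 0.50). Cardiac ion channel and gap junction genes fell (-0.35). Without sham saline library 1 the medians were 0.78 for corticosteroid responsive, 1.37 for inflammation, 0.62 for mitochondrial genome and 1.14 for endothelial genes. Endothelial markers had 0.18 without sham saline library 2 and 0.26 without library 3. Mitochondrial genome genes had a median of 6.8e-05 without sham saline library 2, where they did not pass (adjusted p 0.0985), and 0.09 without library 3. Without library 3, macrophage markers had 0.40 and ion channel genes -0.22. Sgk1 had 1.68 against 1.00, Flt1 1.66 and Fabp4 1.52 without sham saline library 1, Fabp4 0.62 without sham saline library 2, and Oas2 0.94, Ifi44 0.998 and Egr1 0.42 without sham JV001 library 1. Immediate early genes had 0.20 without sham JV001 library 1 and 0.73 without sham JV001 library 3, interferon genes 0.41 without sham JV001 library 1, and macrophage markers 0.13 and inflammation genes 0.55 without sham JV001 library 2.

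For sham JV001 against sham saline edgeR called 0 of 15004 genes, with 426 at an unadjusted p under 0.05, fewer than the 750.2 of chance, and a smallest adjusted p of 0.9997. DESeq2 called 3, all higher, limma on FPKM 0 with either pseudocount and voom 10 (7 higher, 3 lower). Groups did not overlap in 12.4% of genes, where chance gives 10%. The smallest p belonged to Tmem100 (0.96, SE 0.16), at 27.3 ± 4.41 against 14.1 ± 0.639 CPM, Magi3 (-0.71, SE 0.15), Tmem164 (0.61, SE 0.13), Tcf23 (2.72, SE 0.63) and Fam222a (-1.62, SE 0.39). The 426 genes became 894 without sham saline library 1 and 249 without sham JV001 library 1.

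Of the lists, 8 of 35 passed camera there, 7 higher and 1 lower, with none at an estimated correlation (adjusted p 0.976 for each) or with fry. Adjusted over the list alone, 1 mitochondrial genome gene was higher and 0 members of the other 7 passed. Without sham saline library 1, 17 lists passed and without sham saline library 3, 5. Without the latter, ion channel, inflammation, immediate early and macrophage lists were not among them. Inflammation and macrophage lists did not pass without sham JV001 library 2, interferon (median 0.41) and immediate early (0.20) lists without sham JV001 library 1, and mitochondrial genome and endothelial lists without sham saline library 2. Corticosteroid responsive genes passed whichever library was left out.

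CKD JV001 against sham JV001 asked what the CKD model changed when JV001 was injected in both groups. Cenpf, a kinetochore protein of dividing cells, fell to 5.94 ± 1.45 CPM from 25.1 ± 8.13 CPM, Tmem100, a membrane protein, to 9.97 ± 0.556 from 27.3 ± 4.41 CPM and Tmem82 to 8.82 ± 0.522 from 23.4 ± 5.05 CPM (SD, n = 3). Their log2 fold changes were -2.08 (SE 0.27), -1.45 (SE 0.17) and -1.41 (SE 0.17), each at an edgeR adjusted p of 0.0353. In sham saline Tmem100 averaged 14.1 ± 0.639 CPM, below its level in sham JV001. That difference did not pass (edgeR adjusted p 0.9997), but the fall of Tmem100 was measured from the higher of these levels. Extracellular matrix genes rose with a median of 1.498 by camera at its preset correlation, and adjusted over the list alone 16 of 38 were higher. Neither this list nor any other passed in that contrast with an estimated correlation (smallest adjusted p 0.451). Fatty acid oxidation genes fell (median -0.80), with 20 of 31 lower adjusted over the list alone.

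The matrix genes included Ltbp2 at 20.7 ± 6.12 against 1.79 ± 0.460 CPM, Cilp (log2 fold change 3.74, SE 0.71), Comp (3.57, SE 0.81) and Postn (2.11, SE 0.50). Pdk4, a kinase that holds back glucose oxidation, was at 192 ± 69.9 against 1273 ± 906 CPM, Lpl had -1.13 (SE 0.24) and Acot1 -0.94 (SE 0.20). Interferon response (2.04, 26 of 29 higher adjusted over the list alone), inflammation (2.82, 16 of 22) and senescence and secretory genes (1.39, 0 of 20) rose. Psmb9 had 2.13 (SE 0.53), Dhx58 2.32 (SE 0.61), Ccl5 4.45 (SE 0.88) and Vcam1 4.00 (SE 1.13). Ccl5 averaged 0.0786 CPM in sham JV001, below the limit of 3 counts (0.0870 to 0.0918 CPM there), so its fold change is uncertain. Contractile (-0.75, 8 of 26 lower adjusted over the list alone), ion channel (-0.61, 6 of 21), mitochondrial biogenesis (-0.54, 5 of 21), nuclear oxidative phosphorylation (-0.67, 0 of 40), glycolysis (-0.56, 0 of 22) and autophagy genes (-0.21, 0 of 20) fell. Ppara, a receptor that drives fatty acid oxidation genes, had -1.42 (SE 0.26), its coactivator Ppargc1a -1.79 (SE 0.33), Ryr2 -1.28 (SE 0.29), Ttn -1.36 (SE 0.31), the potassium channel Kcnj3 -1.25 (SE 0.31), Cs -1.05 (SE 0.29), Sdha -0.97 (SE 0.28) and Myh6 -1.07 (SE 0.36). With an estimated correlation 0 of these lists passed. Without CKD JV001 library 3 the medians were 0.61 for interferon, 0.62 for inflammation, 0.64 for senescence, -0.47 for contractile, -0.39 for oxidative phosphorylation, -0.30 for glycolysis and -0.09 for autophagy genes, Vcam1 had 1.20 and Dhx58 1.17, and without CKD JV001 library 1 the median of autophagy genes was -0.32.

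Cell type markers changed too, though every ventricular marker is also in the contractile list and several fibroblast markers are in the matrix list. Ventricular markers fell (-0.72, 3 of 12 lower adjusted over the list alone). Markers of fibroblasts (1.65, 11 of 12 higher adjusted over the list alone), macrophages (2.00, 12 of 13), neutrophils (6.10, 6 of 6), erythroid cells (2.88, 5 of 6), smooth muscle and pericytes (1.19, 5 of 11), endothelial cells (1.04, 0 of 12), T and NK cells (2.28, 0 of 6) and B cells (2.08, 0 of 5) rose. Cx3cr1 had 3.59 (SE 0.94), Csf1r 1.94 (SE 0.62), S100a9 5.89 (SE 1.71) and Hbb-bt 2.92 (SE 1.00). With an estimated correlation 0 of these marker lists passed, and without CKD JV001 library 3 the medians were 2.51 for neutrophils, 0.65 for smooth muscle and -0.39 for ventricular markers, and S100a9 had 2.88. Several neutrophil and T and NK cell markers had few reads in sham JV001 libraries 1 to 3. Mmp8 had 0, 4 and 0, Retnlg 0, 8 and 0 and Cd3e 0, 4 and 1, so the size of these medians is uncertain.

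For CKD JV001 against sham JV001 edgeR called 3 genes, all lower, and 4120 of 15004 had an unadjusted p under 0.05. Groups did not overlap in 43.0% of genes, where chance gives 10%. At an adjusted p under 0.1 there were 709 genes. Next in order were Lgals4 (-1.80, SE 0.25) and the proteoglycan gene Cspg4b (-2.06, SE 0.29), each at an adjusted p of 0.0553, and Ltbp2 (3.53, SE 0.51) with the same value. DESeq2 called 2016 genes (1108 higher, 908 lower), edgeR on these 2 groups alone 743 (548 higher, 195 lower), limma on FPKM 74 with a pseudocount of 1 and 10 with 0.1, and voom 4434. These alternatives included the 3 genes. With replicate number as a block edgeR called 0 genes (3684 at p under 0.05), each of the 3 having an adjusted p of 0.0837, and with libraries 1 and 2 of each CKD group summed it called 0 (4009), each having 0.140. Without sham JV001 library 2, 2 genes passed, and 0 passed without sham JV001 library 1, sham JV001 library 3, or any of CKD JV001 libraries 1, 2 and 3. The number at p under 0.05 was 2467 without sham JV001 library 3 and 2692 without CKD JV001 library 3.

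Camera passed 20 of 35 lists in that contrast, 12 higher and 8 lower, none with an estimated correlation (adjusted p 0.451 to 0.630) and none with fry's test in 1 direction (smallest 0.101). Fry's test in either direction passed 5: cell cycle, ion channel, mitochondrial biogenesis, fatty acid oxidation, and renin-angiotensin and natriuretic receptor genes. Calls held without each library except for autophagy (without sham JV001 library 1, adjusted p 0.0728, or CKD JV001 library 3, 0.101) and B cell markers (without sham JV001 library 1, 0.0728). With marker levels of other cells as a covariate, 5 lists passed, all lower, 2 of them among the 20 irrespective of direction, and edgeR called 0 genes.

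The interaction asked whether JV001 acted differently in CKD and in sham. Extracellular matrix genes were shifted upward in CKD, with a median interaction of 1.05 on the log2 scale (36 of 38 positive), and nuclear oxidative phosphorylation (-0.58, 40 of 40 negative) and fatty acid oxidation genes (-0.65, 29 of 31 negative) downward. Fibroblast markers had a median of 1.04, or 0.62 without sham saline library 1 and 1.96 without CKD saline library 3. Ventricular markers had -0.66, or -0.35 without CKD JV001 library 3. With an estimated correlation 0 lists passed (smallest adjusted p 0.612). Matrix genes had 2.02 without CKD saline library 3 and 0.58 without sham saline library 1, and without CKD JV001 library 3 oxidative phosphorylation genes had -0.29 and fatty acid oxidation genes -0.37. Ltbp2 had 2.05 (SE 0.67), Comp 2.35 (SE 1.06), Ndufs1 -0.73 (SE 0.41), Pdk4 -2.56 (SE 0.68) and Cxcl10 5.94 (SE 2.37), which was 0.62 without CKD JV001 library 3, where Ndufs1 had -0.49; Comp had 3.66 without sham JV001 library 2. Single genes did not pass: edgeR called 0 of 15004, with 567 at an unadjusted p under 0.05 and a smallest adjusted p of 0.840, DESeq2 2 (1 higher, 1 lower), limma on FPKM 0 with either pseudocount and voom 20 (10 higher, 10 lower). Among the genes with the smallest p were Tmem100 (-1.18, SE 0.23), Xpnpep2 (3.47, SE 0.72), Lgals4 (-1.59, SE 0.35) and Angptl7 (3.28, SE 0.75). Camera passed 18 of 35 lists, 10 higher and 8 lower, none with an estimated correlation (adjusted p 0.612 to 0.644) or fry, and adjusted over the list alone 0 members passed in these lists. The 567 genes became 2789 without CKD saline library 3, 329 without sham saline library 1, 338 without CKD saline library 1 and 328 without CKD saline library 2. Inflammation (median 0.01, adjusted p 0.519), interferon (0.12, adjusted p 0.204) and macrophage lists (0.23, adjusted p 0.102) did not pass without CKD JV001 library 3, and macrophage markers did not without sham JV001 library 3. Epicardial markers (0.42) did not pass without sham saline library 1. Mitochondrial genome, autophagy, atrial, and T and NK cell lists each failed to pass when 1 of at least 5 different libraries was left out.

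The fold changes of the CKD model were compared with those of JV001 to ask whether JV001 moved genes back. Across 15004 genes, which are not independent replicates, log2 fold changes of CKD saline against sham saline and CKD JV001 against CKD saline had a Pearson correlation of 0.0484 and a covariance of 0.0311. Unchanged groups that share the CKD saline libraries gave -0.507 ± 0.0161 (SD) and a covariance of -0.174 in 50 simulations, so the covariance lay 0.205 above the value of shared libraries alone. These simulations ignored that same-numbered CKD libraries deviated together, and they drew genes independently of each other. Their SD is therefore no measure of the spread expected for correlated genes. On log2 CPM the covariance was 0.0796, and unchanged groups were expected to give -0.164 from shared libraries alone and -0.104 with the pairs, so the excess was 0.244 without and 0.183 with them. Signs were opposite in 35.8% of genes, against 69.4% in the simulations. With 0 genes called by edgeR in each contrast, its calls say nothing of reversal. DESeq2 called 54 and 67 genes, 3 of them in both and in opposite directions, against 0.139 for independent lists; shared libraries alone favour opposite directions. They were Fgf12, Gabrp and Il18r1, named after their values were seen, with means of 0.0916, 0 and 0.0388 CPM in CKD saline. Correlations of log2 CPM differences were 0.185, above the -0.898 to 0.121 of the other random assignments of libraries, which ignored the pairs, and above the -0.866 to 0.0562 of the 7 other swaps within pairs, too few for a share under 0.05. The correlation was 0.437 for genes of at least 10 CPM, -0.354 without a filter on low counts, -0.473 without CKD saline library 3 and 0.244 without sham saline library 1. It was -0.0817 and -0.118 without sham saline libraries 2 and 3, -0.149 and -0.141 without CKD saline libraries 1 and 2, -0.195 without CKD JV001 library 3, and 0.0225 without CKD JV001 library 1. For CKD saline and sham JV001, both against sham saline, the correlation was 0.545 and the covariance 0.234, against 0.496 and 0.170 in simulations, a difference in covariance of 0.0649. Of 100 assignments, 59 gave a correlation as high. Groups of 3 shared libraries cannot be divided into separate sets of 2, so part of this last excess may come from the shared controls, to the extent that their spread exceeded the simulated one; for the other pair, shared libraries act toward a negative covariance.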

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

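The tests in this part, other than those of the gene lists in the interaction, were chosen after the results were seen. The results below stand out because their values with JV001 differed between CKD and sham by camera's test of the interaction at its preset correlation. On the log2 scale the medians were 1.05 for extracellular matrix and fibrosis (adjusted p 7.69e-12), 1.33 for interferon response and DNA sensing (3.27e-08), 1.81 for inflammation and NF-kB (1.12e-05) and 1.02 for senescence and secretory factors (8.93e-05). Energy and muscle genes went the other way: nuclear oxidative phosphorylation -0.58 (3.85e-11), fatty acid oxidation -0.65 (1.02e-10), contractile and calcium handling -0.60 (7.23e-09), glucose uptake and glycolysis -0.49 (7.04e-06), mitochondrial biogenesis -0.44 (5.84e-05), mitochondrial genome protein genes -0.28 (0.0170), and autophagy and mitophagy -0.24 (0.0181). Cell type markers had 1.04 for fibroblasts (1.12e-05), 1.04 for smooth muscle and pericytes (0.000146), 0.76 for macrophages (0.00264), 1.62 for T and NK cells (0.0245), 2.14 for epicardial and mesothelial cells (0.00264), 1.87 for atrial cardiomyocytes (0.0274) and -0.66 for ventricular cardiomyocytes (1.12e-05). With an estimated correlation each adjusted p was between 0.612 and 0.644. Without CKD JV001 library 3, inflammation (0.01, adjusted p 0.519), interferon (0.12, 0.204), macrophage (0.23, 0.102) and autophagy lists (-0.09, 0.178) did not pass. The medians were then 0.43 for senescence, -0.28 for contractile, -0.29 for oxidative phosphorylation, -0.37 for fatty acid oxidation, -0.21 for glycolysis, -0.26 for mitochondrial biogenesis, -0.35 for ventricular and 0.50 for smooth muscle genes. Without sham saline library 1, epicardial (0.42, 0.479), atrial (0.66, 0.668) and T and NK cell markers (0.02, 0.113) did not pass, and matrix had 0.58, fibroblast 0.62, smooth muscle 0.50, macrophage 0.36 and mitochondrial genome genes -0.70. Without CKD saline library 3, matrix had 2.02, inflammation 3.16, interferon 2.03, senescence 1.60, fibroblast 1.96, macrophage 1.86 and T and NK cell markers 2.71. Mitochondrial genome genes did not pass without sham saline library 2 (-0.14) or 3 (-0.15), sham JV001 library 1 (-0.23), CKD saline library 3 (-0.19) or CKD JV001 library 2 (-0.19). Autophagy genes did not without sham saline library 1 (-0.16), sham JV001 library 1 (-0.21), or CKD saline library 1 (-0.18) or 2 (-0.16), and had -0.37 without CKD saline library 3. Mitochondrial biogenesis genes had -0.29 without sham saline library 1 and -0.27 without CKD saline library 1. T and NK cell markers did not without sham JV001 library 1 (1.61), CKD saline library 1 (1.29), or CKD JV001 library 1 (1.73) or 2 (1.66), and had 2.85 without sham JV001 library 2. Atrial markers did not without sham saline library 3 (2.02), sham JV001 library 1 (1.69) or 3 (1.53), CKD saline library 3 (1.81), or CKD JV001 library 1 (1.78) or 2 (1.82). Macrophage markers did not without sham JV001 library 3 (0.41), and had 1.31 without sham JV001 library 2, 0.36 without CKD saline library 1 and 0.48 without library 2. Several T and NK cell markers lay near the limit of 3 counts, such as Cd3e with 0 and 0 reads in CKD saline libraries 1 and 2. The size of their median is therefore uncertain. Of 100 assignments of the 12 libraries, the real one included and the others random, 54 gave at least 18 lists, up to 25, so chance cannot be excluded. The assignments took no account of replicate numbers. For gene calls the assignments cannot test chance, since edgeR called 0 (567 at p under 0.05, 2 by DESeq2) and 100 of 100 must give at least 0. At p under 0.05, other assignments gave up to 5768 genes, above the real 567. In 5 of the random assignments 1 or more genes were called, up to 2520, and what drove these calls was not tested.

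Markers of fibroblasts, macrophages and other cells were higher and ventricular markers lower in CKD JV001 than in CKD saline. A lower share of cardiomyocytes alone, with the other cell types in unchanged proportion, would raise all other markers alike. Fibroblast markers rose by 0.81 more than endothelial markers (rises 1.65 and 0.84), with an SE of 0.15 from the CKD groups and 0.38 from the spread of all 4 groups, and by 0.77, 0.80 and 0.86 in same-numbered libraries. If libraries 1 and 2 of each CKD group are 1 animal, it was 0.82, with an SE of 0.22 from the CKD groups and 0.53 from all 4; this goes against a lower share as the whole cause by all of these but the last, under 2 SE, so it stays open. Fibroblast markers stood at 6.44 and 6.51 log2 CPM in CKD JV001 libraries 1 and 2. Each lay above all CKD saline libraries, at 4.34, 4.32 and 6.29. Without CKD JV001 library 3 the rise was 1.49 (SE 0.66), against 1.65 with it. These values argue against library 3 as the sole source of the fibroblast rise in these libraries. If libraries 1 and 2 are 1 animal the rise was 1.16 (SE 1.04), so whether it exceeds the spread between animals stays open. For ventricular markers, at -0.40 (SE 0.27) without CKD JV001 library 3, that library alone stays open too. Same-numbered differences were -0.67, -0.67 and -1.08 for ventricular and 2.10, 2.19 and 0.65 for fibroblast markers, so each pair moved the same way, but pairs 1 and 2 could be 1 pair of animals, whose agreement gives no spread between animals. Also open are a preparation with more fibroblasts and immune cells and a biological effect in the heart.

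Atrial markers, Nppa among them, were lower in CKD saline than in sham saline. Different amounts of atrial tissue in the preparations could account for this: over 12 libraries Nppa followed the mean of Sln, Myl4, Myl7 and Bmp10 (Pearson r 0.899, permutation p 9e-05; Spearman rho 0.909, permutation p 8e-05; 100000 permutations). Without the 2 farthest libraries, sham saline libraries 2 and 1, r was 0.940. All of these genes are in the atrial list, so the correlation shows only that they varied together. It cannot tell amounts of atrial tissue from a joint change in the expression of these genes. The permutations treated the 12 libraries as independent and ignored the groups. CKD libraries 1 and 2 may share an animal, so the permutation p-values may be too small. Lower natriuretic peptide expression in ventricular cells was left undecided by Nppb, at -0.24 (SE 0.63, adjusted p 0.993).

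CKD saline library 3 lay far from CKD saline libraries 1 and 2. A swap with a library of the CKD JV001 group could put 1 of those nearer to CKD saline libraries 1 and 2 than to its own group, and 0 of 3 were. If libraries 1 and 2 are 1 animal, a library of another CKD saline animal need not lie near them. The test therefore cannot exclude a swap, and a single wrong label stays open too. The lower read total of library 3 is argued against by libraries 1 and 2 thinned to its total, with a Spearman correlation of 0.990 against 0.944 for library 3. CKD saline libraries 1 and 2 may come from 1 animal: the scatter between them at 5000 to 50000 reads was 1.06 times that at 10 to 50 reads, against 6.78 to 295 in 10 other pairs of replicates and 2.34 in CKD JV001 libraries 1 and 2. CKD JV001 libraries 1 and 2 may share an animal too, which 2.34 leaves open. Both remain hypotheses; if they hold, the p-values of contrasts with these groups are too small.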

How the results depend on the processing

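Removing library 3 of both CKD groups, a robust spread, voom with quality weights, summing CKD libraries 1 and 2, and the covariate of other cells' marker levels were chosen after seeing the data. Log2 changes are given as medians for lists. For every change of value below, the cause was not tested. Where leaving a library out leaves fewer samples, fewer calls can follow from that alone. Without its library 3, a CKD group holds libraries 1 and 2, which may come from 1 animal. Calls there may rest on technical spread. The same may hold for voom, which gave libraries 3 of the CKD groups its lowest weights. Across the named genes, of settings fixed beforehand and leaving no library out, 887 values kept direction and side of the threshold, 86 newly passed, 3 no longer passed and 2 turned; for lists, whose direction here is camera's and where lists that passed in neither count as kept, 651 kept both and 181 no longer passed, with a median of changed sign in 0 of 744 values of lists that had passed and 8 of 88 of others. Leaving each library out, 696 gene values kept both, 24 newly passed, 16 no longer passed and 8 turned, and for lists 615 kept both, 76 no longer passed and 5 turned. The sign of the median changed in 8 of 624 values of lists that had passed and in 18 of 72 of the shelterin and telomerase lists that had not, leaving each library out; 3 of the 8 kept camera's direction. Under the added settings these were 434, 112, 6 and 8 for genes, and 299 kept, 64 no longer passed and 21 turned for lists, with a median of changed sign in 26 of 344 and 9 of 40. Scaling to library totals moves each log2 fold change by -0.09 in CKD saline against sham saline, 0.18 in CKD JV001 against CKD saline, -0.00 in sham JV001 against sham saline, 0.09 in CKD JV001 against sham JV001 and 0.18 in the interaction. Depth limits Tert, with 0 to 6 reads per library.

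In CKD saline against sham saline, edgeR called 0 genes (743 at p under 0.05), DESeq2 54, voom 5 and the covariate 3, and leaving out each library 0. Lists numbered 18, with 0 under camera with an estimated correlation, 0 under fry, 9 with library 3 of both CKD groups removed, and 8 (without CKD saline library 3) to 21 leaving each library out. Leaving out each library gave -0.38 to 1.00 for extracellular matrix, -0.23 to 1.13 for fibroblast markers, -0.32 to 0.10 for contractile genes, -0.23 to 0.16 for oxidative phosphorylation, -0.29 to 0.078 for fatty acid oxidation and -0.081 to 0.54 for Terf1. Of these, the values of opposite sign lay in the set without CKD saline library 3. With library 3 of both CKD groups removed, these were -0.38, -0.23, 0.10, 0.16, 0.079 and -0.080, and inflammation -0.27. With the covariate they were -0.36, -0.17, 0.13, 0.16, 0.092 and -0.16, with inflammation -0.47 and interferon -0.13.

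In CKD JV001 against CKD saline, edgeR called 0 genes (2707 at p under 0.05), DESeq2 67, voom 6738, 3043 with library 3 of both CKD groups removed, and 0 to 3287 (without CKD saline library 3) leaving each library out. Lists numbered 22, with 0 under camera with an estimated correlation, 0 under fry, 11 with the covariate and 20 to 22 leaving each library out. Terf1 had 0.15 (without CKD JV001 library 3) to 1.07 (without CKD saline library 3) leaving each library out. With the covariate Terf1 had -0.19, Mrc1 -0.00034, autophagy 0.022, immediate early genes -0.023 and endothelial markers -0.20. With replicate number as a block, immediate early genes no longer passed, and the block changed no other call in this contrast.

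In sham JV001 against sham saline, edgeR called 0 genes (426 at p under 0.05), DESeq2 3, voom 10, and 0 leaving each library out. Lists numbered 8, with 0 under camera with an estimated correlation, 0 under fry, and 5 (without sham saline library 3) to 17 (without sham saline library 1) leaving each library out. Terf2 had -0.00082 with voom and -0.026 (without sham JV001 library 3) to 0.15 leaving each library out. With the covariate inflammation had -0.11, and macrophage markers 0.045 with camera's direction turned.

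In CKD JV001 against sham JV001, edgeR called 3 genes. There were 7 with RLE factors, 5 with no filter on low counts, 12 with the stricter filter, 7 with mitochondrial and haemoglobin genes left out, 743 with only the groups compared, 2016 by DESeq2, 74 and 10 by limma on FPKM with pseudocounts of 1 and 0.1, 1433 with library 3 of both CKD groups removed, 8 with the robust spread and 4434 by voom. There were 0 with the replicate block (3684 at p under 0.05), 0 with CKD libraries 1 and 2 summed (4009), 0 with the covariate (1111), and 0 to 2 (without sham JV001 library 2) leaving each library out. Lists numbered 20, with 5 with the covariate, 0 under camera with an estimated correlation, 0 under fry and 20 to 23 leaving each library out. Terf2 had 0.047 and 0.062 by limma on FPKM, 0.043 with the covariate and -0.13 to 0.032 leaving each library out. With the covariate Terf1 had -0.36, autophagy 0.038, endothelial markers -0.28 and smooth muscle markers -0.18.

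In the interaction, edgeR called 0 genes (567 at p under 0.05), DESeq2 2, voom 20, and 0 leaving each library out. Lists numbered 18, with 0 under camera with an estimated correlation, 0 under fry and 15 to 20 leaving each library out. Terf1 had -0.20 with the covariate and -0.15 (without CKD JV001 library 3) to 0.76 leaving each library out, and Terf2 -0.059 to 0.12. The correlation of the fold changes of CKD with those of JV001 in CKD, 0.0484, was 0.437 for genes of at least 10 CPM, -0.354 with no filter, 0.247 with the stricter filter, -0.0278 with DESeq2 fold changes, 0.514 and 0.449 with FPKM and pseudocounts of 1 and 0.1, -0.524 with library 3 of both CKD groups removed, -0.113 with voom, -0.230 with the covariate and -0.473 (without CKD saline library 3) to 0.244 leaving each library out. With those of JV001 in sham, 0.545 became 0.651 for genes of at least 10 CPM, 0.365 with library 3 of both CKD groups removed and 0.369 to 0.698 leaving each library out.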

Other observations

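The tests on other splits of the libraries in this part were chosen after the results were seen, and the tests of gene lists were not. Several groups of genes did not pass camera in any contrast. The p53 targets and DNA damage response had medians of 0.11 in CKD saline against sham saline and 0.32 in CKD JV001 against CKD saline, then -0.02 in sham JV001 against sham saline, 0.14 in CKD JV001 against sham JV001 and 0.04 in the interaction. In the same order, antioxidant and NRF2 targets had 0.09, -0.17, -0.02, -0.20 and -0.26, circadian clock genes 0.21, 0.02, 0.05, 0.17 and 0.11, renin-angiotensin and natriuretic receptor genes -0.08, 0.24, -0.01, 0.16 and 0.07, and Schwann and neuronal markers -0.25, 0.65, 0.30, 0.43 and 0.68. In CKD JV001 against sham JV001, adjusted over the list alone, 4 antioxidant genes were higher and 4 lower, 2 renin-angiotensin genes higher and 2 lower, 1 clock gene higher and 2 corticosteroid responsive genes lower.

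The share of counts from mitochondrial genes ranged from 18.8% to 38.5% over the 12 libraries, with group means of 24.4 ± 8.99% in sham saline, 27.0 ± 1.81% in sham JV001, 33.0 ± 4.91% in CKD saline and 34.0 ± 3.97% in CKD JV001 (SD, n = 3). Hbb-bs, a haemoglobin gene of red cells, had 356 CPM in CKD saline library 3 against 26.6 and 29.6 CPM in CKD saline libraries 1 and 2.

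Each pair of groups can be divided in 10 ways into 3 and 3 libraries, too few for a share under 0.05. In CKD saline against sham saline, 5 of the 10 splits gave as many lists as the real 18 (highest other 23). For CKD JV001 against CKD saline 2 did (real 22, highest other 22). If the replicate numbers pair the libraries there, 3 other splits part all pairs as the real one does. These gave 17, 17 and 11 lists, and the split with 22 kept libraries 1 of both groups together. The number was 8 for sham JV001 against sham saline (real 8, highest other 21) and 7 for CKD JV001 against sham JV001 (real 20, highest other 23). For gene calls the splits cannot test chance in CKD saline against sham saline, CKD JV001 against CKD saline and sham JV001 against sham saline. There edgeR called 0 (743, 2707 and 426 at p under 0.05, and 54, 67 and 3 by DESeq2), and all 10 of 10 splits must give at least 0 (highest other 0). At p under 0.05, other splits gave up to 2310, 5302 and 931 genes in these contrasts, each above the real number. In CKD JV001 against sham JV001, 1 split, the real one, gave as many as the real 3 (highest other 0). It had 4120 genes at p under 0.05, against up to 814 in the other splits.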
